A study of Mus musculus with 6 samples.

How the data were processed

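Hearts of 6 C57BL/6 mice, 3 wild type and 3 with the lncRNA-DRR deletion, were taken 2 weeks after coronary ligation, frozen, and their RNA was made into libraries with an Illumina TruSeq RNA kit, per the labels. Samples were grouped by genotype as their titles give it, with the replicate numbers of the titles. Nothing in the labels gives a litter, a batch, an operation date, a sex or a time of day for any heart. The labels do not say from how many matings or sessions the mice came, so the p-values measure the spread between these samples.

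The values the authors deposited are FPKM per gene, although the table is titled as counts. Between 37.2% and 40.4% of the values in a library are not whole. In WT replicate 1 and KO replicate 3, which have the highest and the lowest share, all other values are 0. Library totals lie between 442779 and 533319. The most frequent value of FPKM times transcript length in genes with a single transcript differs between libraries (106.4 to 192.7). The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm8 and mm9 without saying what each was used for; the quantification tool, the annotation and any filter are not given in the sources used here, nor is whether strand was used. The table holds 52550 rows keyed by versioned Ensembl gene identifiers. Of these, 52403 matched a gene of GENCODE M21 (GRCm38) by identifier, and 93.3% of all rows matched with the same version, so symbols, gene types and coordinates were taken from that annotation. Its build differs from those in the processing notes; no coordinate was converted.

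That most frequent value was taken as the worth of 1 fragment and gave the approximate depths stated in the results. Only 25.4% to 26.9% of the values below 5 fragments in single-transcript genes came out whole within 0.02 fragments, so whole counts were not recovered, and no interval was built on counts. All 37 mitochondrially encoded genes are listed at 0 in all 6 libraries. At the same time 8 nuclear pseudogenes carry 43.6% to 56.0% of all FPKM in a library. Aligned with blastn (BLAST+ 2.17.0), each of the 8 matched a mitochondrial transcript at 97.6% to 100.0% identity, and 7 of them lie side by side on chromosome 1. FPKM totals therefore move with these rows, whose weight in the scaling factors was limited by trimming. Because genes that every cell uses are listed at 0, a 0 is reported as listed and given per library.

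A count model had been fixed before the data were examined. FPKM values cannot enter it, and limma was used in its place. Genes with an FPKM of at least 0.5 in 3 or more libraries (14656) were kept. Scaling factors were trimmed means of log2 ratios to a reference library (trims of 0.3 on ratios and 0.05 on levels, unweighted) and lay between 0.949 and 1.07. Differences were fitted on log2(FPKM / factor + 0.5) with limma 3.58.1 in R 4.3.3 (genotype as the only term, mean-variance trend, empirical Bayes), two-sided, with Benjamini-Hochberg adjustment over all tested genes, and genes were called at an adjusted p under 0.05. Log2 differences on this scale understate the change of genes with low FPKM. In simulated data for this comparison (14273 genes tested), 57 of 98 genes changed by 1 on the log2 scale and 88 of 97 changed by 2 were recovered, with 12 unchanged genes among 157 calls. The simulated noise was drawn independently for each gene and library, with its spread taken from the mean-variance trend. These rates therefore need not hold for genes that move together or for a library that stands apart.

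Gene lists for the tissue and its cell types, 47 in all, were written before the data were examined. The 44 with 5 or more tested members were tested with camera at its preset correlation of 0.01 (adjusted over the 44 lists). Beside it stand camera with an estimated correlation, fry in its directional and mixed forms, and counts of members called over all genes and adjusted over the list alone. The 3 lists too small to test were those of lung and thymus markers (2 tested members), mitochondrial RNA (0) and sex-linked genes (4). A score per library is the mean deviation of a list's members from their mean over the 6 libraries; scores and summed FPKM were compared by exact permutation, whose smallest two-sided p for 3 against 3 is 0.1.

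Genes to be named were fixed by a rule before the data were examined. It takes the 10 raised and 10 lowered genes with the largest change among those called, with a mean of at least 1 in the higher group, no overlap between groups and a gene name of their own. It adds the 3 members of smallest p of each called list and of 7 fixed lists, and 8 cardiac genes in any case. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen. The rule was written for CPM and was applied to FPKM.

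Alternatives were other scaling factors (median of ratios, upper quartile, none), other filters, other pseudocounts (0.1 and 1), a robust fit, a fit without trend, a fold threshold, a block on the replicate number, each library left out in turn and other tests for the lists. The pseudocounts, the filter at an FPKM of 1, the robust limma fit, the fit without trend and the test without clock and immediate early genes were added after the data were seen. Count tools that had been planned as alternatives were not run because the values are not counts. Antisense and overlapping genes, and rows that share reads with pseudogenes or family members, carry the authors' unstated assignment of reads.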

Results

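RNA from whole mouse hearts was sequenced after myocardial infarction, which was induced at 8 weeks of age by tying off the left anterior descending coronary artery. The 6 C57BL/6 mice fell into 2 genotypes, with 3 wild-type mice (WT) and 3 mice without the long noncoding RNA that the labels call lncRNA-DRR (KO). Hearts were taken at 10 weeks of age, 2 weeks after surgery. All 6 hearts were infarcted, so the single comparison that the design gives is KO against WT in the infarcted heart. The labels give no time of day for any heart, so genotype cannot be separated from a difference in harvest time. Expression values were FPKM (fragments normalised to transcript length and library size). The most frequent product of FPKM and transcript length among genes with a single transcript, taken as the worth of 1 fragment, put the depth at about 9398000, 7955000 and 5189000 fragments for WT replicates 1 to 3 and at about 7037000, 8163000 and 6868000 fragments for KO replicates 1 to 3. Between 14299 and 14869 genes per library had an FPKM of at least 0.5. The noncoding gene Drr1 was listed at 0 in all 6 libraries, and the protein-coding gene Fam107a has the synonym DRR1, but the labels tie neither to the deleted RNA. No row was taken as that RNA, so its level was not analysed here and the genotype labels were not checked by it. KO replicate 3 differed from the other 5 libraries in sex-linked genes: Xist, the noncoding RNA of the inactive X chromosome, stood at 25.6 FPKM there and at 0.0742 FPKM or less in the others. The Y-linked gene Ddx3y stood at 0.0280 FPKM in that library and between 13.0 and 16.2 FPKM in the other 5. By these genes KO replicate 3 reads as female and the other 5 libraries as male, so sex was not balanced between the genotypes.

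Genes of the circadian clock were among those with the largest differences between the genotypes. Because the labels give no time of day, hearts taken at different times cannot be told from an effect of genotype on these genes. Dbp, a transcription factor gene driven by the clock, rose from 1.98 ± 0.30 FPKM in WT to 35.3 ± 6.1 FPKM in KO hearts (SD, n = 3 each). The clock repressor genes Per1, Per2, Per3, Nr1d2 and Ciart rose with it, while Arntl, which encodes the clock activator BMAL1, fell from 7.90 ± 1.72 to 0.68 ± 0.28 FPKM. Npas2, which encodes a partner of BMAL1, fell from 4.34 ± 0.28 to 0.65 ± 0.13 FPKM. Of the 21 measured members of the clock list, 10 rose and 2 fell over all genes tested, and 14 rose and 6 fell when adjusted over the list alone. The list held more called genes than the other tested genes did (Fisher's exact test, two-sided, p = 6.2e-25, across genes, which are not independent replicates).

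On the scale of log2(FPKM + 0.5), on which every log2 difference below is given as KO minus WT ± SE with n = 3 per group, Dbp differed by 3.86 ± 0.16 (limma, adjusted p = 0.00041). The log2 difference was 2.60 ± 0.24 for Per1 (limma adjusted p = 0.0089), 2.16 ± 0.13 for Nr1d2, 2.06 ± 0.15 for Per3 and 2.03 ± 0.15 for Per2 (limma adjusted p = 0.0027, 0.0028 and 0.0028). Ciart differed by 1.94 ± 0.23 (limma adjusted p = 0.026). Among the lowered genes, Arntl differed by -2.83 ± 0.19 and Npas2 by -2.07 ± 0.15 (limma adjusted p = 0.0027 and 0.0028). Dbp lies on chromosome 7 (45705088 to 45710203, plus strand, GRCm38) and Arntl on the same chromosome (113207465 to 113314126, plus strand). As a set the clock list was called up by camera with its preset correlation (adjusted p = 4.0e-10, median log2 difference 1.29), but not with an estimated correlation (adjusted p = 0.149). Each KO library scored above each WT library on this list, which gave the smallest p that an exact permutation test of 3 against 3 allows (two-sided p = 0.1). The calls for Per1 and Ciart did not hold without single libraries: Per1 missed the threshold without KO replicate 1 (limma adjusted p = 0.055), and Ciart without WT replicate 2 or any single KO replicate (0.079 to 0.128).

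**Figure D1:**
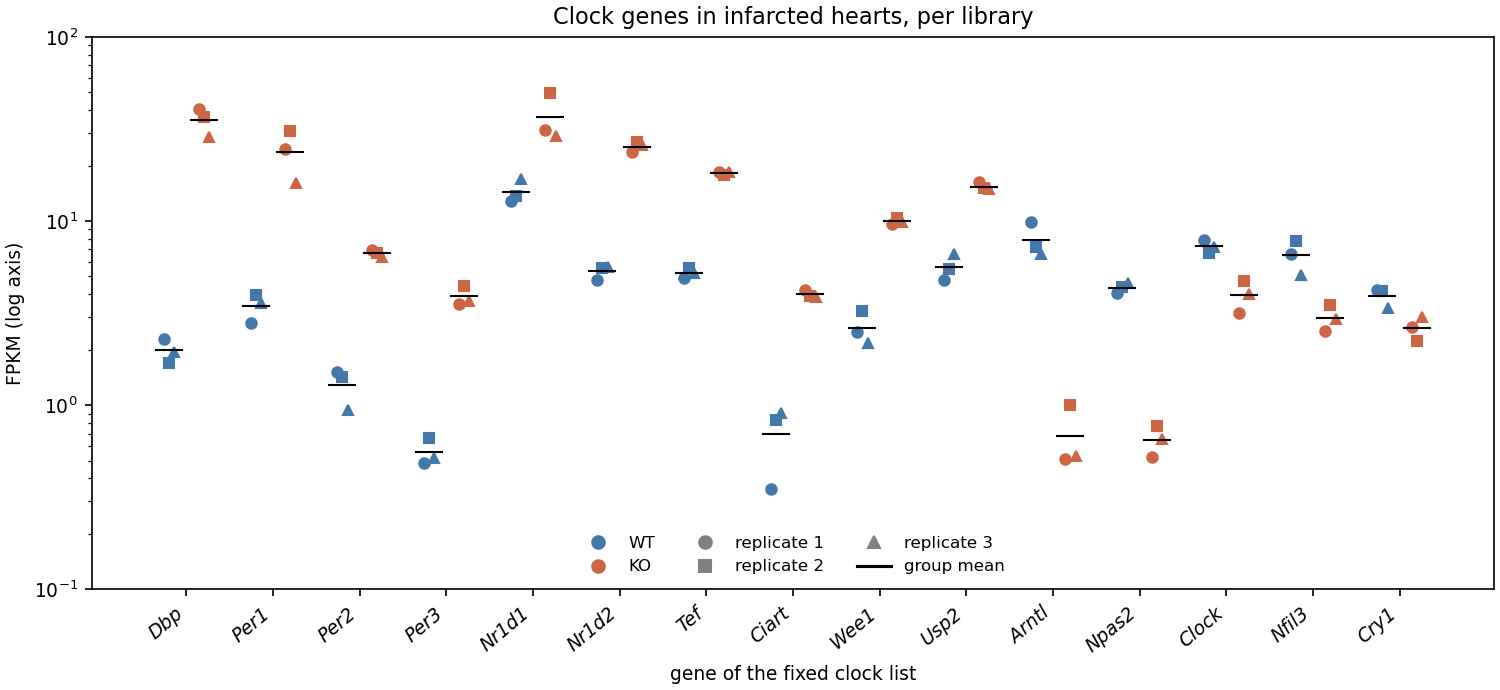
FPKM of 15 members of the clock list on a log axis, with 1 symbol per library (WT blue, KO orange, the shape giving the replicate number) and a bar at each group mean. Dbp stood at 1.70 to 2.29 FPKM in WT and 28.6 to 40.5 FPKM in KO libraries, and Arntl at 6.63 to 9.86 FPKM in WT and 0.51 to 1.01 FPKM in KO libraries.

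Over the whole transcriptome the genotypes differed in few genes. Of 14656 genes tested, 55 were called by limma at an adjusted p under 0.05, of which 40 rose and 15 fell in KO hearts. The change was at least 2-fold for 36 raised and 13 lowered genes among them. An unadjusted limma p under 0.05 was reached by 1243 genes. More genes (1314) reached it when WT replicate 1 and KO replicates 1 and 2 were set against the other libraries. In all 55 called genes the WT and KO libraries did not overlap, which a call from 3 against 3 libraries all but requires, so it adds no support. Over all tested genes the share without overlap was 12.8%, and chance alone gives 10%. The clock list and the list of immediate early genes together held 17 of the 55 called genes, and 38 lay outside both. When one library was left out, the count fell to 26, 16 and 26 called genes without WT replicates 1, 2 and 3, and to 12, 26 and 36 without KO replicates 1, 2 and 3. Mean correlations between libraries were close within genotypes (r = 0.961) and between them (r = 0.955), both across genes.

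Tsc22d3, Depp1 and Fam107a were among the other genes with the largest rises. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, rose from 13.1 ± 1.1 to 67.5 ± 13.5 FPKM (log2 difference 2.31 ± 0.16, limma adjusted p = 0.0027). Depp1 rose by 2.12 ± 0.26 and Fam107a, the gene with the synonym DRR1, by 2.05 ± 0.22 on the log2 scale (limma adjusted p = 0.027 and 0.016). Among the lowered genes outside the clock, Slc41a3, a magnesium transporter gene, fell by 1.75 ± 0.20 on the log2 scale. Rrad, whose GTPase restrains the cardiac L-type calcium channel, went from 114.9 ± 9.6 to 43.1 ± 2.6 FPKM (log2 difference -1.39 ± 0.14, limma adjusted p = 0.016). Foxs1, a forkhead transcription factor gene, differed by -1.23 ± 0.18 (limma adjusted p = 0.050 after rounding, under the threshold). Of these 6 genes, only Tsc22d3 kept its call without any single library. Without KO replicate 1 the adjusted p was 0.095 for Depp1, 0.090 for Fam107a, 0.112 for Slc41a3, 0.090 for Rrad and 0.139 for Foxs1. The calls also ended without WT replicate 1 (Depp1, Foxs1), WT replicate 2 (Depp1, Rrad, Foxs1) or WT replicate 3 (Depp1, Slc41a3, Foxs1). They likewise ended without KO replicate 2 (Depp1, Fam107a, Slc41a3, Foxs1) or KO replicate 3 (Fam107a, Slc41a3, Foxs1).

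Immediate early genes, which respond within minutes to a stimulus, were raised as a group. Of 26 measured members, 5 rose and 0 fell over all genes tested, and 12 rose when adjusted over the list alone. Nr4a1, an orphan nuclear receptor gene, rose from 5.77 ± 1.32 to 20.6 ± 4.2 FPKM (log2 difference 1.76 ± 0.22). Ier3 rose by 1.12 ± 0.12 and Klf6 by 0.94 ± 0.11 on the log2 scale (limma adjusted p = 0.027, 0.016 and 0.026 for the 3 genes in this order). These calls missed the threshold without KO replicate 1, with limma adjusted p of 0.072, 0.095 and 0.139. Each also missed it without several of the other libraries (0.053 to 0.171), Klf6 without any one. The log2 difference of Klf6 stayed between 0.88 and 0.98 in these fits. Fos stood at 2.10 ± 0.56 FPKM in WT and 4.5 ± 1.7 FPKM in KO hearts and was not called (limma adjusted p = 0.237). It was named after its values were seen. The list was called up by camera (adjusted p = 2.1e-16, median log2 difference 0.50), but not with an estimated correlation (adjusted p = 0.090). By fry, which tests whether the genes of a set move on balance in one direction, this list (adjusted p = 0.0073) and the clock list (adjusted p = 0.0052) were the 2 called among 44.

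Of 47 gene lists fixed beforehand, 44 had at least 5 tested members, and camera with its preset correlation called 16 of them, 8 up and 8 down. With an estimated correlation none of the 44 was called, the lowest adjusted p was 0.090 and 4 lists had an unadjusted p under 0.05. In its mixed form, which asks whether members move at all, whatever their direction, fry called 18 lists. The calls described below therefore rest on the preset correlation of 0.01, while the estimates for the called lists ran from 0.015 to 0.77. Calls of other lists with a library left out rest on the same preset. With all 6 libraries the estimate reached 0.91 among those lists, for nuclear genes of oxidative phosphorylation. On the scores per library the genotypes did not overlap for 5 of the 16 lists, those of the clock, immediate early genes, neutrophils, dendritic and mast cells, and cytokines (exact permutation p = 0.1, the smallest possible). They overlapped for the other 11 (exact permutation p from 0.2 to 0.6). For cytokines the gap was narrow, with WT replicate 3 at -0.0563 and KO replicate 2 at -0.0575. Among uncalled lists, those of hypoxia, DNA damage and p53, and vessel wall (mural) cells did not overlap either (exact permutation p = 0.1). Chance alone leaves 10% of lists without overlap.

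Markers of several leucocyte types were lower in KO hearts, though few single genes passed the test. Of 12 measured neutrophil markers 11 were lower, with a median log2 difference of -0.79 (camera adjusted p = 3.3e-07; adjusted p = 0.310 with an estimated correlation). S100a8, a subunit of calprotectin, fell from 8.33 ± 1.74 to 3.17 ± 0.51 FPKM (log2 difference -1.24 ± 0.18, limma adjusted p = 0.047) and was the 1 member called, against 6 when adjusted over the list alone. That call ended without any one of the 6 libraries (limma adjusted p from 0.062 to 0.192), while the log2 difference stayed between -1.38 and -1.13. S100a9, the other subunit, stood at 38.6 ± 8.1 and 15.1 ± 7.0 FPKM, and Mmp8, the neutrophil collagenase, at 1.79 ± 0.14 and 0.62 ± 0.24 FPKM (limma adjusted p = 0.177 and 0.129). Without KO replicate 3 S100a9 was called (log2 difference -1.74, limma adjusted p = 0.034). Of 15 dendritic and mast cell markers 14 were lower (median log2 difference -0.70, camera adjusted p = 1.8e-07; adjusted p = 0.495 with an estimated correlation), none of them called over all genes and 7 when adjusted over the list alone. They included the class II antigen presentation genes Cd74 (log2 difference -0.96 ± 0.23) and H2-Aa (-1.0 ± 0.24) and the mast cell chymase gene Cma1 (-1.26 ± 0.31), with limma adjusted p of 0.213, 0.213 and 0.237. Of 12 T and natural killer cell markers 10 were lower (median -0.34, camera adjusted p = 0.017; adjusted p = 0.834 with an estimated correlation), none called over all genes and 3 when adjusted over the list alone. The T cell receptor genes Trac and Trbc2 differed by -1.04 ± 0.18 and -1.44 ± 0.35, and Lck by -0.85 ± 0.24 (limma adjusted p = 0.091, 0.238 and 0.312). The T cell list was not called without WT replicate 1, WT replicate 2 or KO replicate 1 (camera adjusted p = 0.582, 0.218 and 0.218), nor with the filter at an FPKM of 1 (0.611), which was chosen after the data were seen. On its scores KO replicate 2 (-0.00060) lay above WT replicate 3 (-0.056). Trbc2 was listed at 0 in KO replicates 1 and 3.

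Antibody genes were lower in KO hearts as well. Among 159 tested immunoglobulin genes 149 were lower and 4 fell. These 4 are variable segments, a family whose near-identical members share reads, so the assignment to single segments is uncertain. The 159 are those of 429 immunoglobulin rows that passed the filter on low values, which the 3 WT libraries alone can satisfy. That favours genes higher in WT. Over all tested genes the median log2 difference was -0.004. Igkv3-2 stood at 17.5 ± 2.7 FPKM in WT and 3.19 ± 1.61 FPKM in KO (log2 difference -2.34 ± 0.30, limma adjusted p = 0.029). Ighv5-9-1 stood at 9.67, 5.03 and 3.67 FPKM in the WT libraries and was listed at 0, 0.582 and 0 in the KO libraries, Ighv9-2 at 3.85, 2.34 and 2.73 against 0.391, 0.299 and 0, and Ighv4-1 at 5.76, 2.25 and 2.00 against 0 in all 3 KO libraries (limma adjusted p = 0.024, 0.024 and 0.022). The call of Igkv3-2 ended without any one library except KO replicate 1 (limma adjusted p from 0.083 to 0.114), and that of Ighv5-9-1 without WT replicate 1 or 2 or KO replicate 1 or 3 (0.059 to 0.110). That of Ighv4-1 ended without any one KO replicate (0.064 to 0.095), and that of Ighv9-2 without KO replicate 1 or 2 (0.055 and 0.081); without a WT replicate neither gene passed the filter on low values. The summed FPKM of all immunoglobulin genes was 5086, 2583 and 1415 in the WT libraries and 1381, 985 and 541 in the KO libraries, which did not overlap (exact permutation test on the log scale, two-sided p = 0.1, the smallest possible). The B and plasma cell list had 11 of 13 members lower (median log2 difference -0.83, camera adjusted p = 0.00086; adjusted p = 0.834 with an estimated correlation), 0 called over all genes and 4 when adjusted over the list alone. Its members of smallest p were Jchain (log2 difference -1.52 ± 0.43), Mzb1 (-1.68 ± 0.49) and Iglc1 (-2.83 ± 0.84), with limma adjusted p of 0.312, 0.341 and 0.345. On the scores of this list KO replicate 1 (-0.14) lay above WT replicate 3 (-0.16). The haemoglobin genes, a measure of blood in the tissue, summed to 10998, 7078 and 6280 FPKM in WT and 4555, 4387 and 7246 FPKM in KO libraries (exact permutation p = 0.3). The list of erythroid and platelet markers, which holds haemoglobin genes, had 11 of 13 members lower, none called over all genes or over the list alone (median log2 difference -0.35), and was not called (camera adjusted p = 0.064). It was called down without WT replicate 2, WT replicate 3 or KO replicate 3 (0.011, 0.028 and 0.0085), with the filter at an FPKM of 1 (0.017) and by camera on ranks (0.026).

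The interferon and cytokine lists were called down as well, without a single member called over all genes. Of 41 interferon response genes 37 were lower (median log2 difference -0.21, camera adjusted p = 3.3e-07; adjusted p = 0.834 with an estimated correlation), and 1 passed when adjusted over the list alone. On its scores the genotypes overlapped (exact permutation p = 0.3), with KO replicate 2 (0.15) above WT replicates 1 and 3 (0.13 and 0.059). Isg15, a ubiquitin-like protein gene, stood at 14.3 ± 2.1 FPKM in WT and 7.88 ± 1.56 FPKM in KO hearts (limma adjusted p = 0.106). Tap1, a peptide transporter gene, differed by -0.55 ± 0.16 and Igtp, an interferon-induced GTPase gene, by -0.78 ± 0.25 (limma adjusted p = 0.312 and 0.385). Of 40 cytokine and chemokine genes 29 were lower (median -0.24, camera adjusted p = 0.0096; adjusted p = 0.834 with an estimated correlation), and 4 passed when adjusted over the list alone. The monocyte chemoattractant genes Ccl7 and Ccl12 differed by -1.09 ± 0.18 and -1.10 ± 0.22, and Ccr2, the gene of their receptor, by -1.07 ± 0.22 (limma adjusted p = 0.071, 0.139 and 0.144). Without WT replicate 1 the cytokine list was not called (camera adjusted p = 0.327). The macrophage list was not called (21 of 29 lower, median -0.17, camera adjusted p = 0.056), but it was called down without WT replicate 3, KO replicate 1 or KO replicate 2 (0.00080, 0.049 and 0.0025) and by camera on ranks (0.038).

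**Figure D2:**
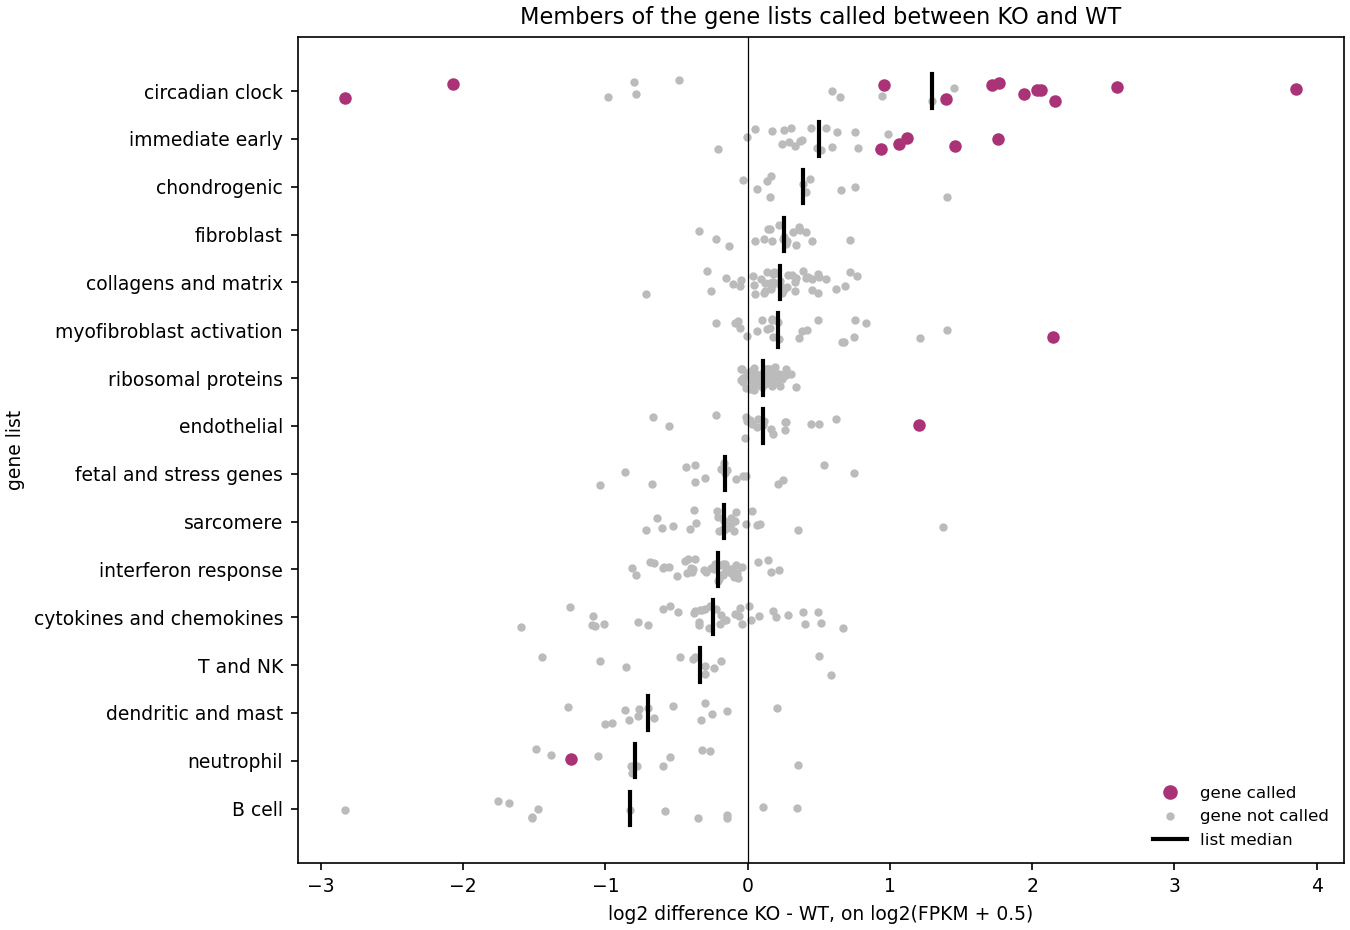
Log2 differences (KO minus WT, on log2(FPKM + 0.5)) of the tested members of the 16 lists called by camera, with 1 point per gene, purple where the gene itself was called, and a black bar at each list's median. The clock list holds 12 called genes on both sides of 0, whereas the interferon list, with a median of -0.21, holds none.

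Matrix and fibroblast genes were higher in KO hearts by small amounts that varied between libraries. Of 47 collagen and matrix genes 40 were higher (median log2 difference 0.22, camera adjusted p = 0.0015; adjusted p = 0.838 with an estimated correlation), and 0 were called, adjusted over the list alone as well. Fbln2 stood at 35.7 ± 8.3 FPKM in WT and 49.3 ± 0.3 FPKM in KO hearts, Mfap5, a microfibril gene, at 32.4 ± 12.8 and 50.5 ± 3.0, and Plod2, a collagen lysyl hydroxylase gene, at 13.9 ± 3.2 and 20.5 ± 6.1 (limma adjusted p = 0.325, 0.385 and 0.507). Col1a1 stood at 189.4 ± 100.9 and 238.5 ± 119.8 FPKM, Col3a1 at 320.2 ± 167.9 and 369.8 ± 166.8, and Postn, an activated fibroblast gene, at 162.1 ± 63.9 and 223.0 ± 70.7 (limma adjusted p = 0.877, 0.914 and 0.708). On the matrix list WT replicate 1 (0.32) and KO replicate 2 (0.54) scored highest among the libraries of their genotypes, and the genotypes overlapped (exact permutation p = 0.5). The matrix list was not called without WT replicate 2, WT replicate 3 or KO replicate 2 (camera adjusted p = 0.065, 0.257 and 0.941). The fibroblast list, with 17 of 20 members higher, none called and none when adjusted over the list alone (median 0.25, camera adjusted p = 0.010; adjusted p = 0.838 with an estimated correlation), was lost without the same libraries (0.065, 0.301 and 0.195). Its genes Tcf21 and Dpep1 differed by 0.36 ± 0.15 and -0.34 ± 0.17 (limma adjusted p = 0.550 and 0.661).

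Of 26 genes of activated fibroblasts 21 were higher (median log2 difference 0.22, camera adjusted p = 3.4e-05; adjusted p = 0.834 with an estimated correlation). Over all genes 1 member rose, and 3 rose when adjusted over the list alone. Chad, which encodes the cartilage protein chondroadherin, stood at 3.27 ± 1.09 and 9.76 ± 4.83 FPKM and Ccn4 at 2.95 ± 0.95 and 7.78 ± 3.78 (limma adjusted p = 0.175 and 0.258). The cartilage and bone list had 10 of 11 members higher, 0 called over all genes and 1 when adjusted over the list alone (median 0.39, camera adjusted p = 0.010; adjusted p = 0.834 with an estimated correlation), and was not called without WT replicate 3 or KO replicate 2 (0.171 and 0.285). In it Sox9 differed by 0.41 ± 0.18 and Cilp2 by 0.75 ± 0.35 (limma adjusted p = 0.622 and 0.641).

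Lists of cardiomyocyte genes showed small median differences, while some of their single genes differed by more. Of 25 sarcomere genes 20 were lower (median log2 difference -0.16, camera adjusted p = 0.048; adjusted p = 0.838 with an estimated correlation), and none was called over all genes. The 5 members that were higher included Tcap, which encodes the titin cap protein telethonin and stood at 504.4 ± 35.0 FPKM in WT and 1304 ± 213 FPKM in KO hearts (log2 difference 1.37 ± 0.22, limma adjusted p = 0.068 over all genes); it was the 1 member past the threshold when adjusted over the list alone. Tcap was called without KO replicate 2 (log2 difference 1.56, limma adjusted p = 0.044) and without scaling factors (limma adjusted p = 0.028). Ankrd23 and Myom2 differed by -0.71 ± 0.18 and -0.60 ± 0.16 (limma adjusted p = 0.249 and 0.294). The sarcomere list was not called without WT replicate 2, WT replicate 3 or KO replicate 2 (camera adjusted p = 0.165, 0.392 and 0.932), and without the last its direction turned. The call was also lost with upper-quartile factors (0.052) and with no filter on low values (0.074). The list of fetal and stress genes had 14 of 18 members lower (median -0.16, camera adjusted p = 0.045; adjusted p = 0.694 with an estimated correlation), none called and 2 when adjusted over the list alone. It was not called without WT replicate 2, WT replicate 3 or KO replicate 1 (0.081, 0.118 and 0.220), nor with upper-quartile factors (0.051), no filter on low values (0.052) or camera on ranks (0.068). Rcan1, an inhibitor of calcineurin, stood at 97.5 ± 5.9 and 47.6 ± 10.6 FPKM and missed the threshold (limma adjusted p = 0.054, or 0.048 with the filter at an FPKM of 1, chosen after the data were seen). Myh7, the slow myosin heavy chain gene, stood at 238.8 ± 47.2 and 146.7 ± 14.4 FPKM and Ccn2 at 190.5 ± 53.1 and 314.8 ± 73.5 (limma adjusted p = 0.225 and 0.317). The natriuretic peptide genes Nppa and Nppb, the fast myosin gene Myh6 and the calcium pump gene Atp2a2 differed by -0.16 ± 0.28, -0.37 ± 0.24, -0.20 ± 0.30 and -0.10 ± 0.24, all less than their spread allowed to call (limma adjusted p = 0.926, 0.762, 0.909 and 0.946).

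**Figure D3:**
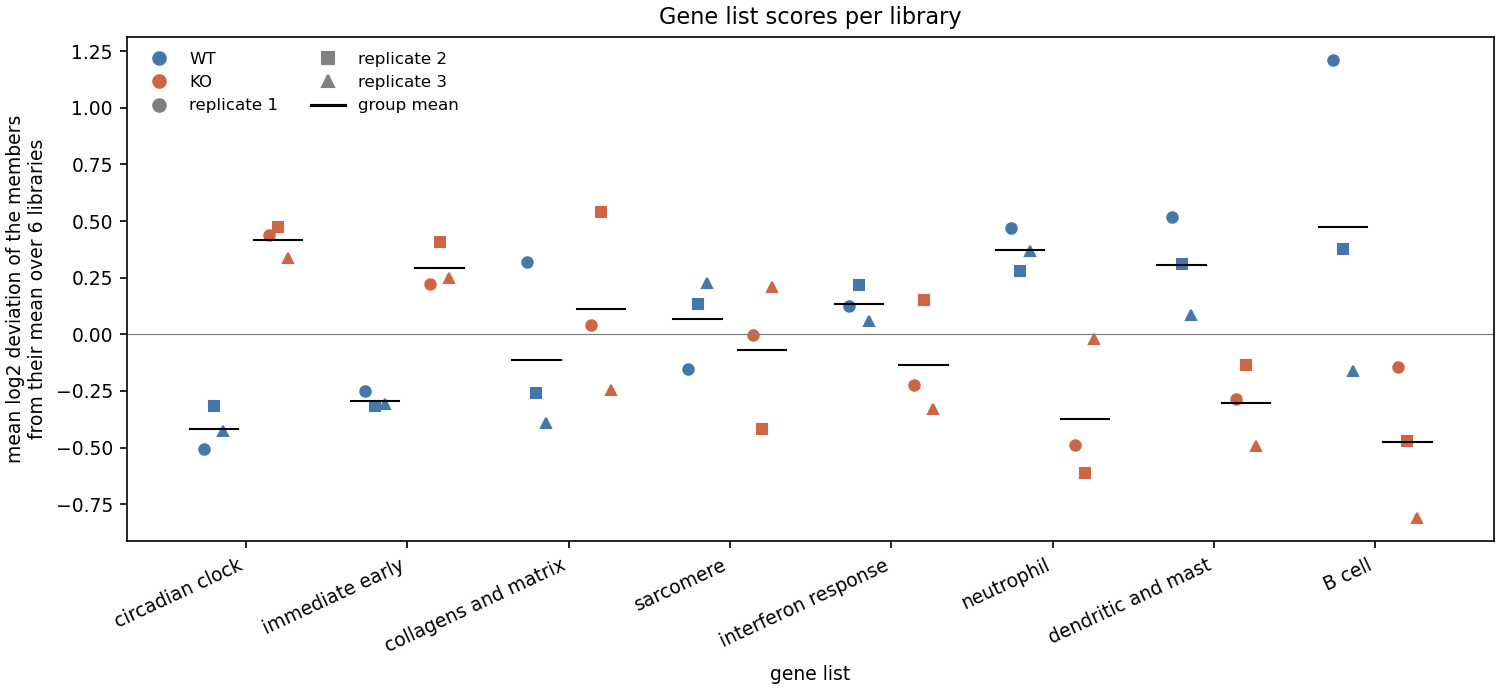
Score of 8 gene lists per library, as the mean log2 deviation of the list's members from their mean over the 6 libraries, with 1 symbol per library (WT blue, KO orange, the shape giving the replicate number) and a bar at each group mean. The genotypes are apart on the clock list (WT -0.50 to -0.32, KO 0.34 to 0.47) and overlap on the matrix list, where WT replicate 1 scored 0.32 and KO replicate 3 scored -0.24.

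Genes of energy metabolism and calcium handling were not called as groups with all 6 libraries. The lists other than that of glycolysis were each called, at the preset correlation of 0.01, when some single libraries were left out. With all 6 libraries the estimated correlation was 0.63 for fatty acid oxidation, 0.91 for oxidative phosphorylation and 0.91 for the tricarboxylic acid cycle. With these estimates the camera adjusted p was 0.840, 0.993 and 0.848. For calcium handling the estimate was 0.093 (camera adjusted p = 0.838). No estimate was made with a library left out. In the fatty acid oxidation list 17 of 37 members were higher, and its median (-0.04) and mean (0.15) differed in sign, the test following the mean (camera adjusted p = 0.137). It was called up without WT replicate 3 or KO replicate 2 (camera adjusted p = 0.011 and 2.3e-07), and its direction turned, without a call, when WT replicate 1 or KO replicate 1 was left out. Ucp3, Pdk4, a kinase gene that shuts off pyruvate oxidation, and Cpt1a, the gateway of fatty acids into mitochondria, differed by 1.56 ± 0.28, 1.62 ± 0.33 and 0.48 ± 0.13, without a call over all genes (limma adjusted p = 0.096, 0.148 and 0.295), and 2 members of the list rose when adjusted over the list alone. In the calcium handling list 17 of 25 members were lower, none called over all genes or over the list alone (median -0.10, camera adjusted p = 0.184), with log2 differences of 0.47 ± 0.14 for Casq1, -0.34 ± 0.12 for Camk2d and -0.33 ± 0.16 for Jph2 (limma adjusted p = 0.351, 0.481 and 0.658). Without WT replicate 1 the calcium handling list was called down (camera adjusted p = 0.023). Of 75 nuclear genes of oxidative phosphorylation 32 were higher (median -0.02, camera adjusted p = 0.844), and the libraries of each genotype lay far apart, with scores from -0.50 in KO replicate 2 to 0.33 in KO replicate 3 and from -0.22 in WT replicate 1 to 0.22 in WT replicate 3. This list was called up without KO replicate 2 (camera adjusted p = 3.3e-09) and down without WT replicate 1 or KO replicate 3 (0.020 and 0.0011), and it turned, without a call, when WT replicate 3 was left out. In the list of the tricarboxylic acid cycle 21 of 27 members were lower, none called over all genes or over the list alone (median -0.10, camera adjusted p = 0.251). It was called down without WT replicate 1, KO replicate 1 or KO replicate 3 (camera adjusted p = 0.0092, 0.042 and 0.0043) and up without KO replicate 2 (0.015), and it turned, without a call, when WT replicate 3 was left out. In the glycolysis list 18 of 25 members were lower, 0 called over all genes and 1 when adjusted over the list alone (median -0.06, camera adjusted p = 0.277), and the list was not called when any one library was left out (0.094 to 0.983). Ribosomal protein genes were higher in 51 of 58 cases by a median of 0.11, none of them called over all genes or over the list alone (camera adjusted p = 0.0018; adjusted p = 0.838 with an estimated correlation). Their reads can be shared with processed pseudogenes. Rps19, Rpl17 and Rpl22 differed by 0.24 ± 0.13, 0.27 ± 0.14 and 0.34 ± 0.19 (limma adjusted p = 0.693, 0.700 and 0.708). The ribosomal list was not called without WT replicate 2, KO replicate 1 or KO replicate 3 (0.078, 0.064 and 0.482).

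Of 21 endothelial markers 15 were higher and 1, Rgcc, rose (median log2 difference 0.11, camera adjusted p = 0.027; adjusted p = 0.834 with an estimated correlation). Rgcc, a cell cycle regulator gene, went from 25.1 ± 5.7 to 57.5 ± 8.4 FPKM (log2 difference 1.20 ± 0.17, limma adjusted p = 0.042). This call ended without any one of the 6 libraries (0.059 to 0.203), while the log2 difference stayed between 1.09 and 1.33. The genes went both ways: Fabp4, a fatty acid binding protein gene, differed by 0.62 ± 0.19, and Kdr, the gene of the main VEGF receptor, by -0.55 ± 0.13 (limma adjusted p = 0.372 and 0.195), and 1 rose and 1 fell when adjusted over the list alone. Without WT replicate 1 or KO replicate 1 the endothelial list was not called (camera adjusted p = 0.243 and 0.119). The 28 lists that were not called included those of cell cycle genes (median 0.04, camera adjusted p = 0.422), hypoxia (median -0.01 and mean 0.19, of opposite sign, camera adjusted p = 0.277), heat shock (median -0.03 and mean 0.03, of opposite sign, camera adjusted p = 0.979) and cardiomyocyte markers (median -0.13, camera adjusted p = 0.124). In the hypoxia list 2 of 27 members rose over all genes tested, and 4 rose when adjusted over the list alone. The cell cycle list was called up without KO replicate 1 (camera adjusted p = 0.00059), and the cardiomyocyte list was called down without WT replicate 1 or KO replicate 3 (0.0028 and 0.0076). Without a call, the direction turned for the cell cycle list without KO replicate 3, for the heat shock list without WT replicate 1 or KO replicate 3, and for the cardiomyocyte list without KO replicate 2.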

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

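One result was marked because a signal outside the comparison stood above its level in the WT libraries. Xist was at 25.6 FPKM in KO replicate 3, against 0.0742 FPKM at most in the WT libraries. In the same library the Y-linked genes Eif2s3y, Kdm5d and Uty were listed at 0, whereas Eif2s3y stood between 12.3 and 13.7 FPKM in the other 5. Without KO replicate 3 the comparison called 36 genes, 27 of them among the 55 called with all libraries, and the clock genes Dbp, Per1, Per2, Per3, Nr1d2, Arntl and Npas2 were called there too. Groups of 3 were not tested for outlying samples, and the series holds no second contrast that could differ from the first.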

How the results depend on the processing

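The genes Dbp, Tsc22d3, Nr1d2, Per3, Per2, Arntl and Npas2 stayed called, in the same direction, under each alternative that tested them; the other 17 of the 24 called genes that the naming rule takes lost the call without at least 1 library, and none of the 24 turned. Over 18 alternatives, 1196 of 1307 values for the 74 genes of the rule kept their direction and side of the threshold, 101 lost a call, 5 gained one and 5 turned. The kept values include 74 for the fold threshold, which repeat the main fit and could not change. Only the 24 called genes could lose a call, so the 101 losses fall on them alone. The 55 calls (40 raised, 15 lowered) became 20 (17 and 3) with no filter on low values, where more genes are tested. They became 26 (18 and 8) without the clock and early genes, a test chosen after the data were seen. Leaving out 1 library gave 12 to 36 genes (9 to 27 raised, 3 to 9 lowered), where fewer samples are fitted. The other scalings, pseudocounts, the stricter filter, the robust fit, the fit without trend and the fold threshold kept the count of genes within 1.5 times.

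With the replicate number as a block, 42 genes were called, 24 raised and 18 lowered, of which 30 were among the 55, and 13 of the 16 lists, without those of the sarcomere, fetal and stress genes and endothelium. Chad gained a call there. Deviations from the group means of libraries with the same number correlated at 0.0076, -0.036 and 0.180, and 2 of 6 libraries correlated best with their own number. No pairing by number was seen, but so few pairs cannot exclude it.

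Of the 16 lists (8 up, 8 down), 0 were called with an estimated correlation (0 up, 0 down) and 2 by fry (2 up, 0 down). Estimated correlations of the 16 lists ran from 0.015 (fetal and stress genes) to 0.77 (sarcomere), above the preset 0.01. How far these account for the lost calls was not tested. Lists called down ranged from 6 to 13 when a library was left out. Within-group minus between-group correlation was 0.0065 over all tested genes and 0.0747 over the 500 most variable. Uncalled genes that turned when a library was left out were Col3a1 (-0.0448 to 0.596), Myh6 (-0.406 to 0.0224), Atp2a2 (-0.274 to 0.101) and Nppa (-0.441 to 0.0168); the cause was not tested. The planned count tools (edgeR, DESeq2 and voom) were not run on FPKM. Depth limits genes near an FPKM of 0.5.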

Other observations

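All tests of explanations below were chosen after the results were seen. A list of 24 genes known to be induced by glucocorticoids, written after the values were seen, had 20 of its 23 tested members higher in KO hearts, with a median log2 difference of 1.00, and 8 rose. It is not separate from the lists fixed beforehand, which hold 9 of the 23, Per1 of the clock list and Dusp1 of the immediate early list among them. Without the genes of these 2 lists 18 of 21 were higher, with a median of 0.96, and 6 rose. Cebpd rose by 1.66 ± 0.14 on the log2 scale, Mt2 by 1.77 ± 0.18, Sgk1 by 1.29 ± 0.16 and Klf9 by 0.96 ± 0.13. Other members went the other way or were not called: Fkbp5 differed by 0.54 ± 0.17, Zbtb16 by -0.72 ± 0.22 and Lcn2 by -0.82 ± 0.18. Called genes outside the lists described so far, also named after their values were seen, included Sik1 (log2 difference 1.80 ± 0.11), a kinase gene induced by cAMP, the endothelial gene Apold1 (1.68 ± 0.12), the potassium channel gene Kcna5 (1.14 ± 0.14) and the sphingosine receptor gene S1pr1 (1.04 ± 0.12). Leo1, a subunit of the PAF1 transcription complex, fell by 1.17 ± 0.15.

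Among rows above 0.3 FPKM in each library of one genotype, 12 were listed at 0 in all 3 KO libraries and 3 in all 3 WT libraries. The 12 included 4 immunoglobulin segments and Gm15523, an antisense gene on chromosome 12 (GRCm38) at 0.837, 0.917 and 1.32 FPKM in the WT libraries. Gm15523 was called (limma adjusted p = 0.050 after rounding, under the threshold). Whether strand was used in the counting is not given, and if it was not, such reads cannot be told from those of the opposite gene.

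The split of the hearts by genotype called 55 genes, and the highest of the other 9 splits called 4. As many were called in 1 of 10 splits, that by genotype itself. Genes with an unadjusted limma p under 0.05 numbered 1243 in that split and 1314 in the highest of the others. For the lists 6 of the 10 splits called at least the 16 of the real one, and the highest other split called 26. With 10 splits no share under 0.05 can be had.

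The clock genes moved in both directions, with 14 members higher and 6 lower past the threshold when adjusted over the list alone. Loss of ARNTL-driven transcription would lower the genes that ARNTL drives; of the 20 members other than Arntl 10 rose and 1 fell over all genes tested, which argues against it for those 10. A glucocorticoid response that left the clock in place would leave clock genes outside the glucocorticoid list uncalled. Of the 20 such genes, 11 were called. That list was written after the values were seen, but of the 21 clock members it holds Per1 alone. The 11 called genes, 9 raised and 2 lowered, argue against this explanation for those genes, as far as that list is complete. A glucocorticoid signal that acted on the clock stays open. A shifted clock phase may underlie the pattern and stays open: it needs members that move both ways, and 6 fell, but the phase of each member was not fixed before the values were seen, so the signs cannot support it. Hearts taken at different times of day and the deleted RNA acting on the clock cannot be told apart either, because 0 of the 6 samples carry a time of day in their labels.

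The lists of neutrophils, dendritic and mast cells, T cells, B cells, interferon response and cytokines were called down in KO hearts by camera with its preset correlation, but none was with an estimated correlation (adjusted p from 0.310 to 0.834), and of their members S100a8 alone was called, a call that ended without any one library. WT replicate 1 had the highest immunoglobulin total, but without it the median log2 difference of 142 immunoglobulin genes was -0.84 and 86.6% of them were lower. For these genes that argues against WT replicate 1 as the whole cause. Without that library the T cell and cytokine lists were not called (camera adjusted p = 0.582 and 0.327). The lists of neutrophils, dendritic and mast cells, B cells and interferon response stayed called down. Less blood left in the KO hearts could contribute and stays open: haemoglobin differed by -0.59 ± 0.34 on the log2 scale, with overlapping groups, against -1.55 ± 0.66 for immunoglobulin, and the erythroid and platelet list had 11 of 13 members lower without a call (camera adjusted p = 0.064, from 0.0085 to 0.582 when a library was left out). An effect of the deleted RNA stays open as untested.

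The matrix list was called up and the sarcomere list down in KO hearts by camera with its preset correlation, but neither with an estimated correlation (adjusted p = 0.838 for both). No member of either was called over all genes, Tcap differed by 1.37 ± 0.22 against the direction of its list, and the sarcomere list turned without KO replicate 2. This may follow from different amounts of scar in the libraries of both groups: the matrix score gave an exact permutation p of 0.5, and in each genotype the library with the most matrix, WT replicate 1 and KO replicate 2, had the least sarcomere. An effect of the deleted RNA on scar cannot be told apart from this scatter, since the matrix score differed by 0.224 with a 95% interval from -0.65 to 1.10.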
